A study of Arabidopsis thaliana with 42 samples.

How the data were processed

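The values analysed were the deposited counts per locus, which the submitters' processing notes describe as tag counts from Smart-3SEQ libraries. Per the labels' protocols, plants grew for 30 days at 22 °C, 75% relative humidity and 12 h of light, a Pma suspension of OD600 0.0002 or 5 mM MgSO4 was put into leaves 6 to 8, and 2 leaves made a sample 24 h later. Per the submitters' processing notes, reads were made with bcl2fastq 2.17.1.14, lost the 5-base molecular tag and the GGG after it (8 bases), and were aligned with STAR 2.4.2a to TAIR10. The counting tool, the annotation release, the strand setting, the use of the molecular tag to remove copies and the mutant alleles were not given in the sources used here. Reads were not analysed here. Values of paralogs and of genes that overlap another gene therefore carry a caution: GIP2 lies at chromosome 1, start 27744649, end 27745429 of TAIR10.1 and overlaps the end of SARD1 (start 27744790, end 27749248).

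The table held 24843 loci and 42 libraries, none left out, and 164 loci had no count at all. The reference was TAIR10.1, in which 24701 loci were found by locus name and 9956 had a symbol, and the other genes are named by locus. The values are whole numbers, and between replicates the chi-square per degree of freedom was 3.38 to 38.51 (42 pairs), above counting error alone. Intervals and bounds of folds at low counts cover counting error only.

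The test was the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with legacy = FALSE, glmQLFTest) with TMM factors and filterByExpr (min.count 10, min.total.count 15) in R 4.3.3. A single fit of all 42 libraries held 14 groups and the experiment as a block (16 coefficients, 26 residual degrees of freedom), and 27 comparisons were contrasts of it. Calls needed Benjamini-Hochberg adjusted p under 0.05 over 15161 genes, and the SE is the absolute log2 fold change divided by the square root of F. The tests, groups, gene lists and alternatives were written down before the data were examined. The block was taken because the design puts 1 sample of each group in each experiment. After removal of group means, libraries of the same experiment correlated at 0.372, 0.351 and 0.133 (91 pairs each). The replicate numbers thus pair the libraries across groups, least clearly in experiment 3. Libraries of different experiments were at -0.142 (546 pairs), which follows from the removal of group means and is no separate evidence.

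Lists held 283 loci: salicylic acid biosynthesis and signalling, salicylic acid response markers, camalexin and tryptophan pathway, pattern recognition, jasmonate, abscisic acid, ethylene, nuclear-encoded photosynthesis, endoplasmic reticulum protein folding, aliphatic glucosinolates, calmodulin-like and CBP60 families, senescence, guard cell, phloem, epidermis and reference genes, besides the 7 mutated genes. They were written from general knowledge. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and again with the correlation estimated. The response size used genes that passed and moved at least 2-fold in the average response of all 7 genotypes, and its exact test compares 3 experiments with 3. Similarity used Pearson correlation over all tested genes, and 100 simulated data sets with the shared wild type libraries and no effect gave the value to compare with. The sign-flip test of the response size and the similarity of chp60g sard1 with the triple mutant and of wrky70 with sid2 were added after the results were seen, as was the covariance of effects from different experiments, where each mutant is set against the wild type library of its own experiment.

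Genes were named by a fixed rule. It takes the mutated genes in every comparison, the 10 strongest rises and 10 strongest falls (5 and 5 between genotypes) with adjusted p under 0.05, a mean of at least 5 CPM in the higher group, the same direction in all 3 experiments and a reference symbol, and from each list the 4 members with the lowest adjusted p past the threshold. PR1, ICS1, FMO1, ALD1 and PAD3 were named whatever their p. Genes outside the rule are said to be chosen after their values were seen. Levels (CPM) are counts scaled to the library size after TMM, and the prior count of log2 CPM was 2. A group with no count of a gene was given 3 counts over its 3 libraries to form a bound.

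Alternatives were RLE factors, no filter (genes with at least 1 count), no block, DESeq2 1.42.0, fits of the mock or Pma libraries alone, a trended dispersion from estimateDisp (chosen after the data were seen), and fits without 1 experiment or 1 library. All splits of the 6 libraries of a comparison into 3 and 3 (10 splits, 4 of which part all 3 pairs) were fitted as well. Figures were made with Python 3.11.15 and matplotlib 3.10.9.

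A self-test simulated 42 libraries in 3 experiments with changes in sid2 mock. Of 50 genes each at 1.5, 2, 4 and 8-fold, edgeR recovered 0, 12 (24%), 39 (78%) and 49 (98%), and 5 of 14820 genes without a change were called. No recovered gene had the wrong direction.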

Results

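The data described transcript levels in leaves of Arabidopsis thaliana Col-0 and of 6 lines labelled as mutants of genes acting in salicylic acid defence, after inoculation with Pseudomonas syringae pv. maculicola ES4326 (Pma) or after a mock treatment with 5 mM MgSO4. Counts of 3' tags were given for 24843 loci in 42 libraries, which formed 14 groups (7 genotypes, 2 treatments) of 3 libraries each. Each library came from 1 of 3 independent experiments, and every experiment held all 14 groups, so n = 3 means 3 experiments throughout. The genotypes were wild type, cbp60a, chp60g sard1 (the spelling of the label, read here as cbp60g sard1), cbp60a cbp60g sard1 (the triple mutant), cml46 cml47, wrky70 and sid2. Libraries held 919335 to 2691069 counts (median 1588053.5) and detected 16494 to 18859 loci. Wild type held 1241254 to 1710141 counts in mock and 1042600 to 1637213 in Pma, cbp60a 919335 to 1729566 and 961263 to 1770457, and chp60g sard1 1115498 to 2129360 and 1029735 to 2112811. The triple mutant held 991795 to 1570526 counts in mock and 1139523 to 1773712 in Pma, cml46 cml47 1593876 to 2691069 and 1129794 to 1879847, wrky70 1514202 to 1873416 and 1136205 to 1739172, and sid2 1485505 to 1610656 and 1344477 to 2102624. The first principal component carried 71.5% of the variance and the second 6.7%.

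Levels are mean CPM (counts scaled to the size of the library) ± SD with n = 3. Effects are fitted log2 fold changes ± SE from edgeR with the experiment as a block, and p-values were adjusted over the 15161 tested genes. In fits with libraries left out, each library was left out alone. A named gene had the same direction in all 3 experiments unless another number is given. Where 1 of 2 compared groups held no more than 3 counts of a gene, a lower bound or a ratio with its 95% interval of counting error replaces the fitted fold, and such genes are given no value for a difference in response.

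The first question was what became of the mutated genes themselves. CML46, a calmodulin-like protein, reached 335 ± 137 CPM in wild type Pma leaves but 0.473 ± 0.427 in cml46 cml47, a level 621-fold lower (212 to 3020, adjusted p = 1.21e-11). ICS1, which makes isochorismate for salicylic acid, was at 542 ± 203 CPM in wild type Pma and 1.94 ± 1.13 in sid2 (-8.06 ± 0.60, adjusted p = 7.77e-11). SARD1 and CBP60G, related transcription factors that drive ICS1, were at 250 ± 30.8 and 255 ± 18.1 CPM in wild type Pma. Both were lower in chp60g sard1 (SARD1 -4.62 ± 0.60, adjusted p = 3.98e-06, CBP60G -2.72 ± 0.42, adjusted p = 4.33e-05) and in the triple mutant (-4.47 ± 0.60, adjusted p = 8.19e-06, and -3.20 ± 0.43, adjusted p = 8.63e-06). WRKY70, a transcription factor of salicylic acid responses, was lower in wrky70 Pma leaves (-3.55 ± 0.54, adjusted p = 0.000268, 153 ± 63 CPM against 1820 ± 166). CBP60A, a calmodulin-binding relative of CBP60G, was lower in the triple mutant in Pma (-1.05 ± 0.25, adjusted p = 0.00522), whereas in cbp60a it was at -1.18 ± 0.25 without passing (adjusted p = 0.192, 20.1 ± 4.22 CPM against 46.2 ± 14.1). CML47, the second calmodulin-like gene, kept 229 ± 55.3 CPM in cml46 cml47 Pma against 682 ± 112 (-1.58 ± 0.47, adjusted p = 0.173).

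In mock leaves CML46 was 13.6-fold lower in cml46 cml47 (3.22 to 121, adjusted p = 0.0184) and ICS1 lower in sid2 (-3.78 ± 0.67, adjusted p = 0.0219). The other mutated genes did not pass there: CBP60A in cbp60a (-0.89 ± 0.27, adjusted p = 0.156) and in the triple mutant (-0.82, adjusted p = 0.413), WRKY70 in wrky70 (-1.87 ± 0.54, adjusted p = 0.186) and CML47 in cml46 cml47 (0.58, adjusted p = 0.7, 2 of 3 experiments). SARD1 was at 1.12 (adjusted p = 0.829, 2 of 3 experiments) in chp60g sard1 mock and 0.79 in the triple mutant, and CBP60G at 0.42 and 0.01, from levels of only 3.75 ± 0.822 and 5.71 ± 6.36 CPM in wild type. A 3' tag outside the changed part of a gene checks nothing about the allele, and the alleles were not given in the sources used here. Tags from CBP60A, CBP60G and CML47 that remained in their mutants could come from a transcript that is made but not functional, or from reads of a relative.

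The second question was how wild type leaves responded to Pma at 24 h. PR1, a secreted marker protein of salicylic acid defence, rose from 3.36 ± 1.69 to 6250 ± 1550 CPM (11.10 ± 1.55, adjusted p = 2.07e-07). FMO1, which makes N-hydroxypipecolic acid, rose at least 1100-fold (839 ± 61 CPM against 0), and the protease inhibitor gene KTI1 4250-fold (762 to 168000). The pipecolic acid gene ALD1 (9.73 ± 1.00), the camalexin gene PAD3 (9.29 ± 0.86) and the salicylic acid gene PBS3 (7.63 ± 0.63) rose as well. At least 631-fold, 504-fold and 374-fold rises were seen for GSTU3 (a glutathione transferase), SBT3.3 (a subtilase) and UGT76B1 (a glucosyltransferase for salicylic acid). Among the largest falls, the wall enzyme gene XTH31 fell at least 183-fold, the expansin gene EXPA5 at least 137-fold and the aldolase gene FBA5 1220-fold (417 to 5920).

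Of 15161 tested genes, 10051 changed in wild type (4900 higher, 5151 lower). In the list of salicylic acid biosynthesis and signalling, 21 of 22 genes rose (median 4.45), with ICS1 at 4.86 ± 0.48 (adjusted p = 2.99e-10), and 17 of 20 response markers rose and 1 fell (median 4.14), among them the glutaredoxin gene GRX480 (247-fold, 84.1 to 1200). All but 1 of 14 camalexin and tryptophan genes rose (median 4.42), with ASA1 at 4.81 ± 0.34, and 25 of 30 jasmonate genes rose and 1 fell (median 4.18), with the repressor JAZ1 at 6.10 ± 0.48. All 14 genes of protein folding in the endoplasmic reticulum rose (median 3.15), with the chaperone BIP2 at 4.29 ± 0.42. All 43 nuclear-encoded photosynthesis genes fell (median -3.56), with the photosystem gene PSAN at 184 ± 9.69 CPM against 5810 ± 973. In the calmodulin-like and CBP60 families 18 of 27 rose and 4 fell (median 3.83, or 3.61 with genes at 0 placed at their bound), with CML47 at 7.25 ± 0.65, CML46 at 6.21 ± 0.55, SARD1 at 6.06 ± 0.68, CBP60G at 5.44 ± 0.50 and CBP60A at 1.07 ± 0.25. WRKY70 rose by 4.2 ± 0.56 (adjusted p = 9.26e-08).

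Among smaller lists, 19 of 23 pattern recognition genes rose (median 2.27), with the receptor partner BAK1 at 2.05, as did 9 of 10 senescence genes (median 2.71) with SAG13 at 8.92 ± 0.90. Ethylene genes rose in 8 of 12 cases and fell in 1 (median 1.72), with the oxidase ACO4 at 3.82 ± 0.34. The aliphatic glucosinolate list had 11 of 16 genes lower and 2 higher (median -3.18), with the regulators MYB28 at -4.43 ± 0.60 and MYB29 at -5.26 ± 0.67. Abscisic acid genes went both ways (9 rose, 6 fell of 20, median 0.24, list adjusted p = 0.291). All 5 epidermis genes fell (median -3.70) with the lipid transfer gene LTP1 at -5.90 ± 0.80, while 2 of 7 phloem genes fell (median -0.38, list adjusted p = 0.387) and 1 of 5 guard cell genes rose and 3 fell (median -0.97, list adjusted p = 0.578). The reference genes were at a median of 0.28, with 1 of 4 rising.

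The camera test of limma called 12 of 15 lists in wild type at its preset correlation of 0.01, and none with the correlation estimated from the data. The calls it lost were salicylic acid biosynthesis (adjusted p = 3.55e-09, adjusted p = 0.0951 with an estimated correlation), the response markers (0.000104, 0.245), camalexin (2.77e-10, 0.0951), pattern recognition (2.97e-07, 0.0951) and jasmonate (1.39e-08, 0.127). The others were ethylene (0.0207, 0.265), photosynthesis (3.57e-18, 0.154), protein folding (1.81e-08, 0.127), aliphatic glucosinolates (0.0437, 0.57), the calmodulin families (6.6e-06, 0.0951), senescence (8.73e-05, 0.0951) and the epidermis (0.00162, 0.127).

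**Figure D1:**
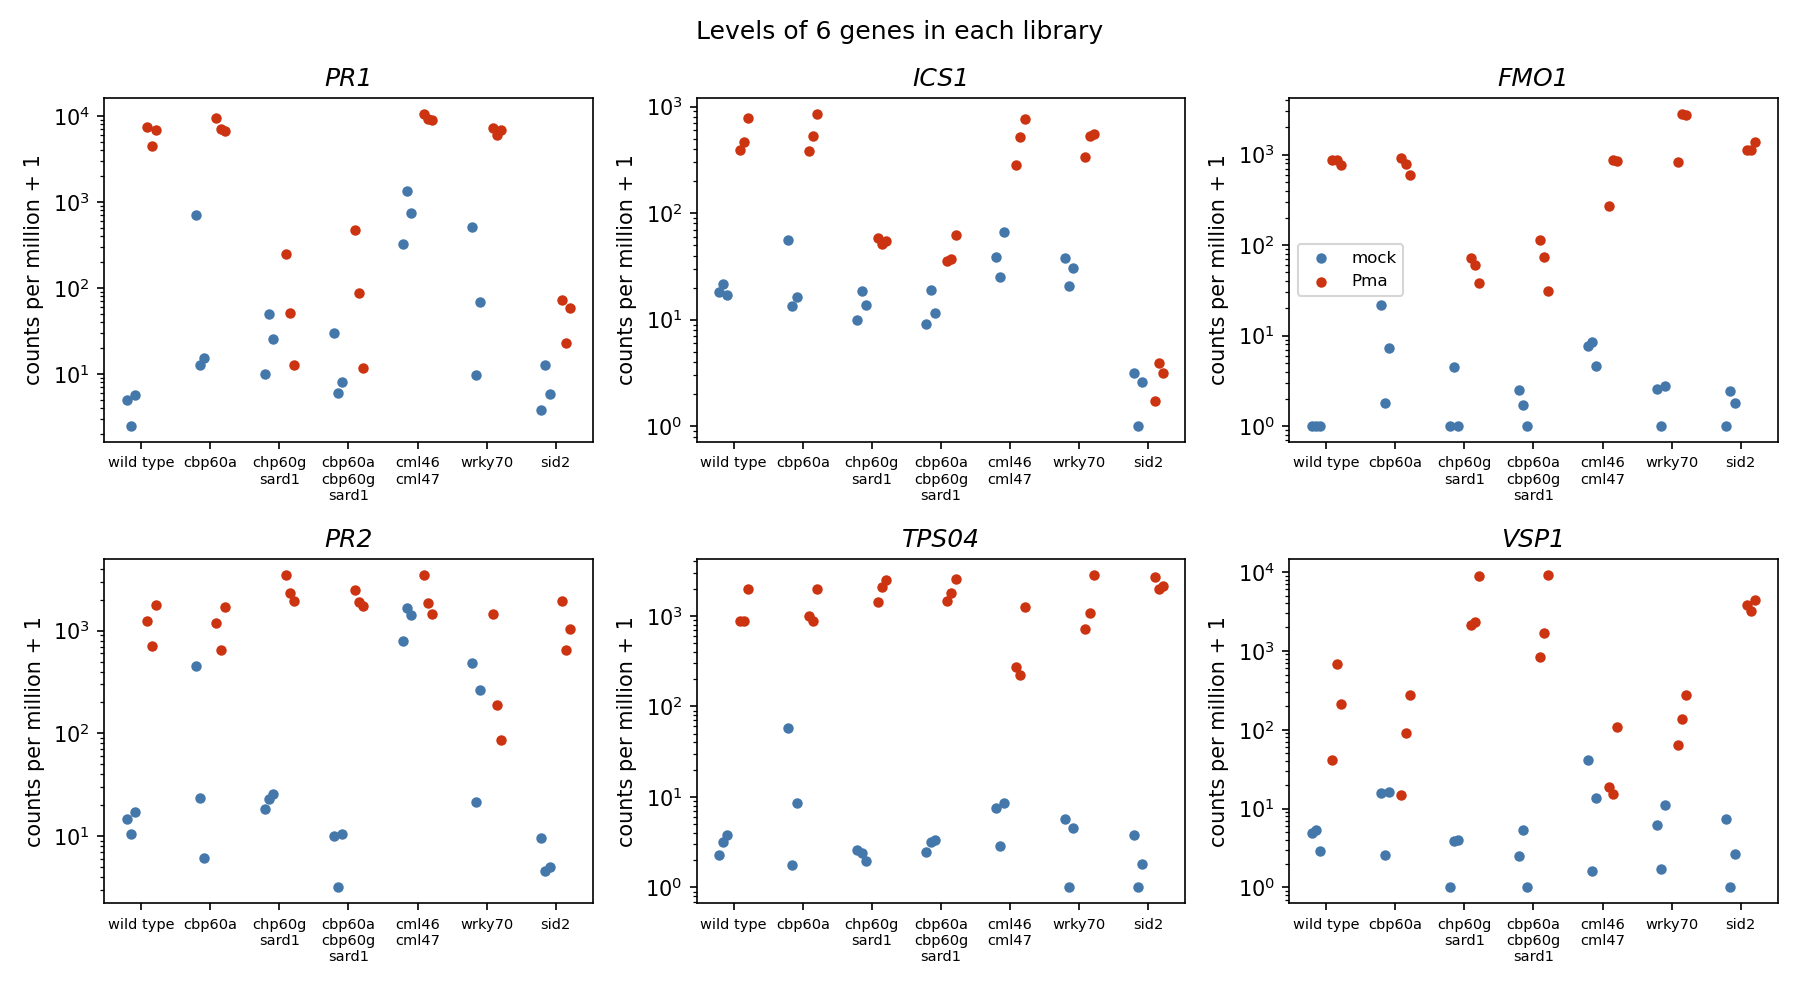
Levels of 6 genes in each of the 42 libraries, as CPM plus 1 on a log axis, with mock in blue and Pma in red. Each point is 1 library, and wild type PR1 averaged 3.36 CPM in mock and 6250 CPM in Pma.

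The third question was how far each mutant kept this response. In cbp60a PR1 rose by 5.88 ± 1.19 (7750 ± 1560 CPM against 244 ± 399) and ICS1 by 4.24 ± 0.46, with 9585 genes changed (4507 higher, 5078 lower). Among them the nitrate transporter gene NRT1.8 rose at least 44.3-fold and the expansin gene EXPA8 fell at least 207-fold. Of the wild type calls, 4115 were higher and 4611 lower in both genotypes, and 1 had the opposite sign. Camalexin genes rose in 13 of 14 cases (median 3.73, adjusted p = 0.0596 with an estimated correlation), and all 43 photosynthesis genes fell (median -3.96, adjusted p = 0.11 with an estimated correlation). For abscisic acid genes the median (-0.09) and mean (-0.01) were opposite in sign to the test, which did not pass (adjusted p = 0.541).

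In chp60g sard1 the rise of PR1 did not pass (1.1 ± 1.07, adjusted p = 0.393, 2 of 3 experiments, 103 ± 127 CPM against 27.2 ± 19.7). ICS1 rose by 2.04 ± 0.46 (adjusted p = 0.000314) and FMO1 by 5.50 ± 0.82, while ALD1 (8.06 ± 0.95) and PAD3 (7.92 ± 0.76) rose strongly. The terpene synthase gene AT2G24210 rose at least 1690-fold, the methionine sulfoxide reductase gene MSRB7 5220-fold (936 to 206000), the storage protein gene VSP1 by 11.04 ± 1.39 and BSMT1, which methylates salicylic acid, by 11.06 ± 1.04. PR2, a glucanase that also serves as a salicylic acid marker, rose by 6.85 ± 0.99. In total 8699 genes changed (4211 higher, 4488 lower), with 3541 higher and 3952 lower as in wild type and 48 opposite. Of the jasmonate genes 28 of 30 rose and 2 fell (median 5.01, adjusted p = 0.0799 with an estimated correlation), whereas only 8 of 20 response markers rose and 1 fell (median 1.03, list adjusted p = 0.222). All 14 camalexin genes rose (median 3.75), a list call that held with the estimated correlation (adjusted p = 0.0389).

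In the triple mutant PR1 rose by 3.47 ± 1.16 (adjusted p = 0.011, 188 ± 246 CPM against 13.7 ± 13.3) and ICS1 by 1.76 (adjusted p = 0.00172), and the ascorbate enzyme gene MDHAR rose at least 1010-fold. The amidohydrolase gene ILL5 and the glucosidase gene BGLU27 rose at least 399-fold and 256-fold, and FMO1 90.5-fold (30.7 to 441). Changes passed for 8843 genes (4213 higher, 4630 lower), of which 3599 and 4088 were shared with wild type and 32 were opposite. Camalexin genes rose in 14 of 14 cases (median 4.25, adjusted p = 0.0226 with an estimated correlation) and jasmonate genes in 27 of 30 (median 5.24, adjusted p = 0.0611 with an estimated correlation). Response markers rose in 11 of 20 cases (median 1.67, list adjusted p = 0.0337, adjusted p = 0.574 with an estimated correlation). For abscisic acid the median (-0.14) and the mean (0.41) differed in sign.

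In cml46 cml47 PR1 rose by 3.36 ± 1.04 (adjusted p = 0.00648) from a mock level that was already 795 ± 508 CPM, and reached 9630 ± 870. FMO1 (6.86), GSTU3 (8.92 ± 0.78) and the jasmonate-regulated gene JRG21 (8.38 ± 0.77) rose, and the auxin conjugation gene BRU6 rose 528-fold (94.2 to 20900). The auxin-induced gene SAUR29 fell at least 21.7-fold and the stomatal peptide gene STOMAGEN at least 16.8-fold. Changes passed for 8662 genes (4077 higher, 4585 lower). Only 18 of 30 jasmonate genes rose (median 1.59, adjusted p = 0.215 with an estimated correlation), against 19 of 22 salicylic acid genes (median 2.7, adjusted p = 0.132 with an estimated correlation). Guard cell genes had a median of -0.28 and a mean of -0.30 while the test pointed up without passing (adjusted p = 0.755), and abscisic acid genes had a median of -0.46 and a mean of 0.06.

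In wrky70 PR1 rose by 5.87 ± 1.18 (adjusted p = 7.45e-05), FMO1 by 10.73 ± 0.85 and the sterol desaturase gene CYP710A1 at least 617-fold. The dioxygenase gene DOX1 rose at least 339-fold. Changes passed for 9197 genes (4436 higher, 4761 lower), including 13 of 14 camalexin genes (median 4.64, adjusted p = 0.0589 with an estimated correlation) and all 10 senescence genes (median 3.13, or 2.68 at the bounds, adjusted p = 0.105 with an estimated correlation). In sid2 PR1 rose by only 2.82 ± 1.23 (adjusted p = 0.0458, 49.9 ± 25 CPM against 6.42 ± 4.57) and ICS1 did not pass (0.58, adjusted p = 0.591, 2 of 3 experiments). FMO1 rose 1640-fold (560 to 7940) in sid2, ALD1 by 9.41 ± 0.96, PAD3 by 8.77 ± 0.80 and the alcohol dehydrogenase gene ELI3-2 at least 1890-fold. Changes passed for 9484 genes (4708 higher, 4776 lower). Camalexin (14 of 14 rose, median 4.34) and senescence (10 of 10 rose, median 3.80) were both called with the estimated correlation (adjusted p = 0.0358 each), while response markers rose in 10 of 20 cases and fell in 3 (median 1.56, list adjusted p = 0.0844).

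The size of the response was compared on 3287 genes that rose and 4255 that fell at least 2-fold. The median rise was 2.09 ± 0.18 in wild type (SD, n = 3), 1.87 ± 0.43 in cbp60a, 1.77 ± 0.04 in chp60g sard1, 1.83 ± 0.02 in the triple mutant, 1.46 ± 0.19 in cml46 cml47, 1.82 ± 0.42 in wrky70 and 2.1 ± 0.12 in sid2. The median fall was -2.30 ± 0.05 in wild type and -2.22 ± 0.20, -1.74 ± 0.23, -1.81 ± 0.28, -1.74 ± 0.25, -1.92 ± 0.44 and -2 ± 0.16 in the mutants in that order. Exact tests of 3 against 3 cannot go below p = 0.1, and exact sign-flip tests of the 3 differences within experiments not below 0.25, so neither test could pass at this n. Their unpaired p was 0.1 except for the rise in cbp60a (0.5), wrky70 (0.6) and sid2 (0.9) and the fall in cbp60a (0.8). Within experiments the rise in cml46 cml47 was smaller than in wild type in 3 of 3 cases (difference -0.63 ± 0.08, SD, exact sign-flip p = 0.25), as it was in chp60g sard1 (-0.33 ± 0.22) and the triple mutant (-0.26 ± 0.17). The fall was smaller in 3 of 3 experiments in chp60g sard1 (0.56 ± 0.26), the triple mutant (0.49 ± 0.32), cml46 cml47 (0.56 ± 0.20), wrky70 (0.38 ± 0.39) and sid2 (0.30 ± 0.21, exact sign-flip p = 0.25 for each).

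**Figure D2:**
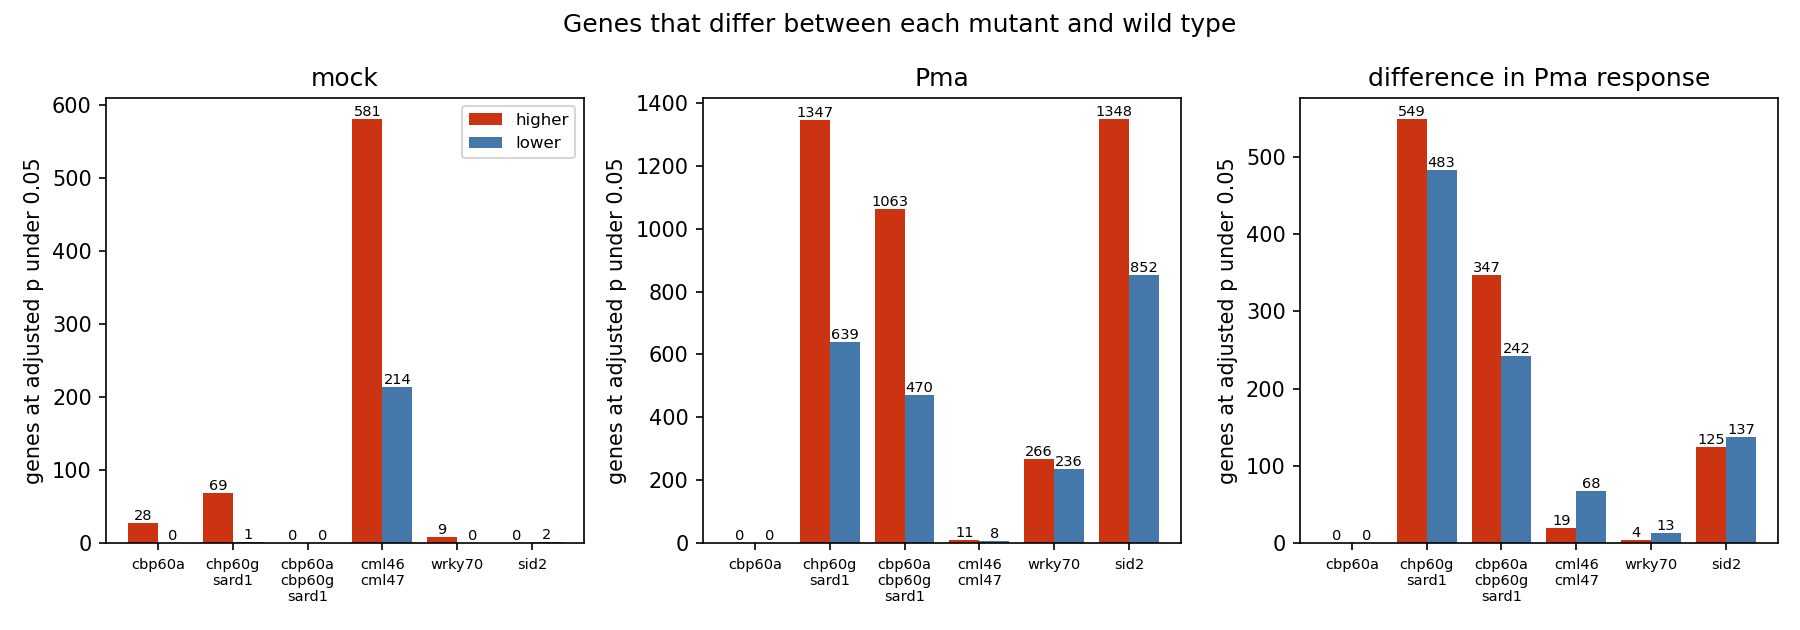
Genes that differ between each mutant and wild type at adjusted p under 0.05, as bars of higher (red) and lower (blue) genes in mock, in Pma and in the difference in response. The largest bars are 1348 genes higher in sid2 Pma and 1347 higher in chp60g sard1 Pma.

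The fourth question was which genes differed from wild type in mock leaves. The cml46 cml47 leaves expressed defence genes without infection: PR1 was at 795 ± 508 CPM against 3.36 ± 1.69 (8.38 ± 1.45, adjusted p = 0.000602), PR2 at 1290 ± 455 against 13.1 ± 3.29 (6.90 ± 1.01, adjusted p = 0.000113) and PR5, a thaumatin-like protein, 5.21 ± 0.81 higher. The oxygenase genes DLO1 and DMR6, which hydroxylate salicylic acid, were at least 71-fold and 3.70 ± 0.58 higher. The calcium exchanger CAX3 (6.46 ± 0.83), the chitinase gene CHI (6.92 ± 0.95), SARD1 (3.29 ± 0.66, adjusted p = 0.00237), CBP60G (2.39 ± 0.49, adjusted p = 0.0028) and FMO1 (at least 7.3-fold, adjusted p = 0.0231) were higher. Neither ICS1 (1.18, adjusted p = 0.123), ALD1 (3.32, adjusted p = 0.0632) nor PAD3 (3.08, adjusted p = 0.0519) passed. Lower genes included the cytokinin regulator ARR15 (14.4-fold, 4.42 to 74), XTH31 (-2.96 ± 0.51) and the chalcone synthase gene TT4 (-2.80 ± 0.66).

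In that comparison 795 genes differed (581 higher, 214 lower), 315 without the block and 2157 in a fit of the mock libraries alone. The luminal chaperone BIP3 was 63.2-fold higher (11.1 to 2520) and the calreticulin CRT3 was at 418 CPM against 93.7, and 11 of 14 folding genes were higher, 14 when adjusted over the list alone (median 1.29, adjusted p = 0.0523 with an estimated correlation). Salicylic acid genes were higher in 8 of 22 cases (14 adjusted over the list alone, median 1.4, adjusted p = 0.0651 with an estimated correlation), and response markers in 6 of 20 (11 adjusted over the list alone, median 1.76, adjusted p = 0.0651 with an estimated correlation). The calmodulin families (6 of 25 higher, median 1.08, CML41 at 4.68 ± 0.74, adjusted p = 0.0297) and the guard cell genes (1 of 5 lower, median -0.78, TGG1 at -1.12 ± 0.32, adjusted p = 0.0299) held with the estimated correlation. Jasmonate genes were higher in 5 of 30 cases (median 1.2, or 1.02 at the bounds, adjusted p = 0.243 with an estimated correlation). None of 43 photosynthesis genes passed alone, although the list did (median -0.52, adjusted p = 3.19e-06, adjusted p = 0.437 with an estimated correlation). Omission of wild type mock replicate 1 gave 363 genes, cml46 cml47 mock replicate 2 gave 416, wild type mock replicate 3 gave 291 and cml46 cml47 mock replicate 3 gave 247.

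The chp60g sard1 mock leaves had higher WRKY70 (2.41 ± 0.52, adjusted p = 0.025, 557 ± 267 CPM against 108 ± 57.2) and its relative WRKY54 (2.39 ± 0.45, adjusted p = 0.0129). The P450 gene CYP81K2 was 23.7-fold higher (3.9 to 972), the lipid-binding protein gene ORP1A 12.2-fold (3.87 to 61.5), the wall-associated kinase WAK1 2.28 ± 0.52 and the calmodulin-like gene AT2G41090 1.61 ± 0.36 (1260 ± 139 CPM against 413 ± 29.4). The golgin gene GC6 was lower (-1.07 ± 0.22, adjusted p = 0.0169). PR1 (3.45, adjusted p = 0.462) and ICS1 (-0.46, adjusted p = 0.925) did not pass. Altogether 70 genes differed (69 higher, 1 lower), 10 without the block and 132 in a fit of the mock libraries alone. Response markers were higher in 2 of 20 cases, 11 when adjusted over the list alone (median 2.05, adjusted p = 0.0864 with an estimated correlation). Leaving out wild type mock replicate 1, 2 or 3 gave 0, 19 and 0 genes, and leaving out chp60g sard1 mock replicate 1 or 3 gave 27 and 0.

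In cbp60a mock leaves 28 genes were higher and none lower. FMO1 was at least 14.4-fold higher (9.26 ± 10.2 CPM, adjusted p = 0.0489), the receptor-like gene RLP40 29-fold (7.66 to 245, 11.1 ± 17.4 CPM), GRX480 22.5-fold (7.36 to 112, 12.9 ± 20.5 CPM) and the jasmonate gene AOC3 3.42 ± 0.76. These intervals leave out the spread between libraries, which for RLP40 and GRX480 was larger than the mean. PR1 did not pass (5.50 ± 1.39, adjusted p = 0.0663), with 705, 11.7 and 14.1 CPM in the 3 libraries, nor did PAD3 (3.77, adjusted p = 0.0623), ALD1 (3.45, adjusted p = 0.175) or ICS1 (0.73, adjusted p = 0.78), each in 2 of 3 experiments. Response markers were higher in 2 of 20 cases, 15 adjusted over the list alone (median 1.72, adjusted p = 0.0663 with an estimated correlation). No gene was called without the block or with RLE scaling, 1295 genes were at unadjusted p under 0.05, DESeq2 called 134 and a fit of the mock libraries alone 59. The count went to 0 without any 1 of wild type mock replicates 1, 2 and 3 and without cbp60a mock replicate 1, and to 119 and 304 without cbp60a mock replicates 2 and 3.

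For wrky70 mock leaves 9 genes were higher, all 9 of them also higher in cml46 cml47 mock (0.3 by chance if the comparisons shared no wild type libraries). CAX3 (5.03 ± 0.84, adjusted p = 0.0102), CHI (4.59 ± 0.95, adjusted p = 0.0488), the cell expansion gene EXO (2.95 ± 0.55) and DMR6 (2.79 ± 0.57) were among them, while PR1 (5.36, adjusted p = 0.125) and SARD1 (2.98, adjusted p = 0.0728) did not pass. Without the block 3 genes were called, DESeq2 called 56 and a fit of the mock libraries alone 139. Dropping wild type mock replicate 1, 2 or 3 gave 0 each, and leaving out wrky70 mock replicate 1, 2 or 3 gave 0, 74 and 3. In sid2 mock leaves 2 genes were lower, ICS1 and AT1G75945 (-7.40, adjusted p = 1.2e-05), the second of them chosen after its value was seen, and the response markers stayed at a median of -0.02. The mock libraries alone gave 21 genes in sid2. Removal of wild type mock replicate 1 or 2, or sid2 mock replicate 1, 2 or 3, gave 1 gene each.

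In the triple mutant no gene passed in mock. edgeR found 1073 genes at unadjusted p under 0.05, DESeq2 called 15 and a fit of the mock libraries alone 13, and PR1 was at 1.89 (adjusted p = 0.863) and WRKY70 at 1.94 (adjusted p = 0.217). Taking out triple mutant mock replicate 2 or 3 gave 10 and 4 genes. Aliphatic glucosinolate genes had a list call (median -0.32, adjusted p = 0.0456, adjusted p = 0.646 with an estimated correlation) with no member called, and without experiment 1 the direction turned (adjusted p = 0.911).

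The fifth question was which genes differed from wild type in infected leaves. In chp60g sard1 PR1 was at 103 ± 127 CPM against 6250 ± 1550 (-6.55 ± 1.22, adjusted p = 0.000414), ICS1 at 53.8 ± 3.8 against 542 ± 203 (-3.28 ± 0.44, adjusted p = 4.58e-06) and FMO1 at 55.9 ± 16.9 against 839 ± 61 (-3.93 ± 0.58, adjusted p = 1.6e-05). The dioxygenase DOX1 was 186-fold lower (33 to 7380), the pigment regulator MYB90 57.9-fold (10 to 2320) and the glutaredoxin GRXS13 lower by -5.15 ± 0.63. ALD1 (-1.47, adjusted p = 0.112) and PAD3 (0.34, adjusted p = 0.736, 2 of 3 experiments) did not pass. The P450 gene CYP81F4 of indole glucosinolates was at least 86.4-fold higher, XTH18 47.9-fold (12.9 to 402) and BGLU22, a glucosidase, 5.32 ± 0.63. The jasmonate gene AOS reached 1830 ± 548 CPM against 334 ± 109 (2.43 ± 0.32, adjusted p = 3.91e-06).

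In total 1986 genes differed (1347 higher, 639 lower), and 1171 without the block. Salicylic acid genes were lower in 7 of 20 cases and higher in 1 (10 and 2 adjusted over the list alone, median -1.05). Response markers were lower in 5 of 20 (median -0.91), with the hydrolase NUDT6 at -3.58 ± 0.66 and WRKY53 at -2.36. Jasmonate genes were higher in 11 of 30 cases (19 adjusted over the list alone, median 1.23). Photosynthesis genes were higher in 38 of 43 (median 1.53), with RBCS3B at 2.07 ± 0.41, which is a smaller fall, and aliphatic glucosinolate genes in 9 of 16 (median 1.92) with BCAT4 at 3.02. Epidermis genes were higher in 3 of 5 cases (median 2.25), with the wax genes KCS6 at 2.7 ± 0.56 and CER1 at 2.57 ± 0.80 and LTP1 at 2.25 ± 0.70. All 6 lists were called at the preset correlation, and none with an estimated correlation (adjusted p = 0.41 each). For camalexin the median was -0.02 and the mean 0.24, and for ethylene the median was 0.10 and the mean 0.55 while the test pointed down. A fit without wild type Pma replicate 1 gave 1245 genes, wild type Pma replicate 3 gave 1151 and chp60g sard1 Pma replicate 3 gave 832.

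The triple mutant was compared with wild type next. PR1 (-5.74 ± 1.18, adjusted p = 0.0015), ICS1 (-3.62 ± 0.44, adjusted p = 2.65e-06), FMO1 (-3.58 ± 0.57, adjusted p = 6.23e-05) and CML47 (-1.62, adjusted p = 0.0235) were lower, DOX1 was 60.8-fold lower (20.5 to 298) and the laccase gene LAC7 47.5-fold. CYP81F4 was at least 59.8-fold higher, the glucosidase PYK10 5.04 and AOS 2.29 ± 0.32, while ALD1 (-1.47, adjusted p = 0.128) and PAD3 (0.50, adjusted p = 0.616) did not pass. Altogether 1533 genes differed (1063 higher, 470 lower), and 861 without the block. With chp60g sard1 it shared 947 higher genes (94.4 by chance) and 367 lower genes (19.8 by chance), and none had the opposite sign. The effects correlated at r = 0.92, against 0.49 in simulated data with the same shared wild type libraries and no mutant effect (covariance 0.5 against 0.0628, difference 0.437). With effects from different experiments, which share no library, the mean covariance was 0.423 (0.276 to 0.583 over 6 pairings). This argues against the shared controls as the source of the excess. Salicylic acid genes were lower in 8 of 20 cases (median -1.21), response markers in 6 of 20 (median -1.19), and photosynthesis genes were higher in 38 of 43 (median 1.52). With an estimated correlation these list calls were lost (adjusted p = 0.373, 0.413 and 0.373). Epidermis genes were higher in 2 of 5 cases (median 1.77, list adjusted p = 0.0594). Omission of wild type Pma replicate 1 gave 837 genes, wild type Pma replicate 3 gave 786 and triple mutant Pma replicate 3 gave 496.

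In sid2 Pma leaves PR1 was at 49.9 ± 25 CPM (-7.06 ± 1.24, adjusted p = 0.000277). The membrane protein gene PCR1 was at 39.4 CPM against 6510 (-7.42 ± 1.03), the dioxygenase gene ARD3 at 1.51 against 725 (-8.84 ± 1.07, adjusted p = 1.32e-06), UGT76B1 lower by -6.20 ± 0.75 and the marker PCC1 by -4.60 ± 0.63. WRKY70 (-2.63 ± 0.52, adjusted p = 0.000981) and SARD1 (-1.73 ± 0.51, adjusted p = 0.0186) were lower and CBP60A higher (0.72 ± 0.24, adjusted p = 0.0352). FMO1 (0.54, adjusted p = 0.537), ALD1 (0.20) and PAD3 (0.53) did not pass. The protease SAG12 of senescence was at least 35.1-fold higher, the glucosinolate gene CYP81F4 at least 18.9-fold, the ethylene and jasmonate regulator ORA59 20-fold (5.17 to 171) and the cold-induced COR15A 3.38.

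In that comparison 2200 genes differed (1348 higher, 852 lower), and 1127 without the block. Response markers were lower in 13 of 20 cases (median -2.41, list adjusted p = 2.71e-12, adjusted p = 0.217 with an estimated correlation), with WRKY62 at -5.16 ± 0.71. Salicylic acid biosynthesis and signalling genes were lower in 8 of 21 cases and higher in 1 (median -0.52, list adjusted p = 0.000197, lost at adjusted p = 0.327 with an estimated correlation). Jasmonate genes were higher in 12 of 30 cases and lower in 1 (median 1.18), with AOS at 1.80 ± 0.31, abscisic acid genes higher in 8 of 20 (median 1.26), photosynthesis genes in 32 of 43 (median 1.27) and senescence genes in 5 of 10 (median 0.96) with the chlorophyll genes PPH at 1.26 and NYC1 at 1.31. The jasmonate, abscisic acid, photosynthesis and senescence calls were lost as well (adjusted p = 0.327 with an estimated correlation, and 0.261 for senescence). Epidermis genes were higher in 2 of 5 cases (median 1.57, list adjusted p = 0.085). Leaving out wild type Pma replicate 1 gave 1360 genes, sid2 Pma replicate 2 gave 1338 and wild type Pma replicate 3 gave 1242. With chp60g sard1 it shared 663 higher genes (119.8 by chance) and 220 lower (35.9 by chance), and 7 were opposite. The effects of both mutants correlated at r = 0.66, against 0.49 in simulated data with the same shared wild type libraries and no mutant effect (covariance 0.384 against 0.063, difference 0.321). With the effects of both mutants taken from different experiments, so that no library was shared, the covariance was 0.332 on average over 6 pairings (0.22 to 0.479).

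**Figure D3:**
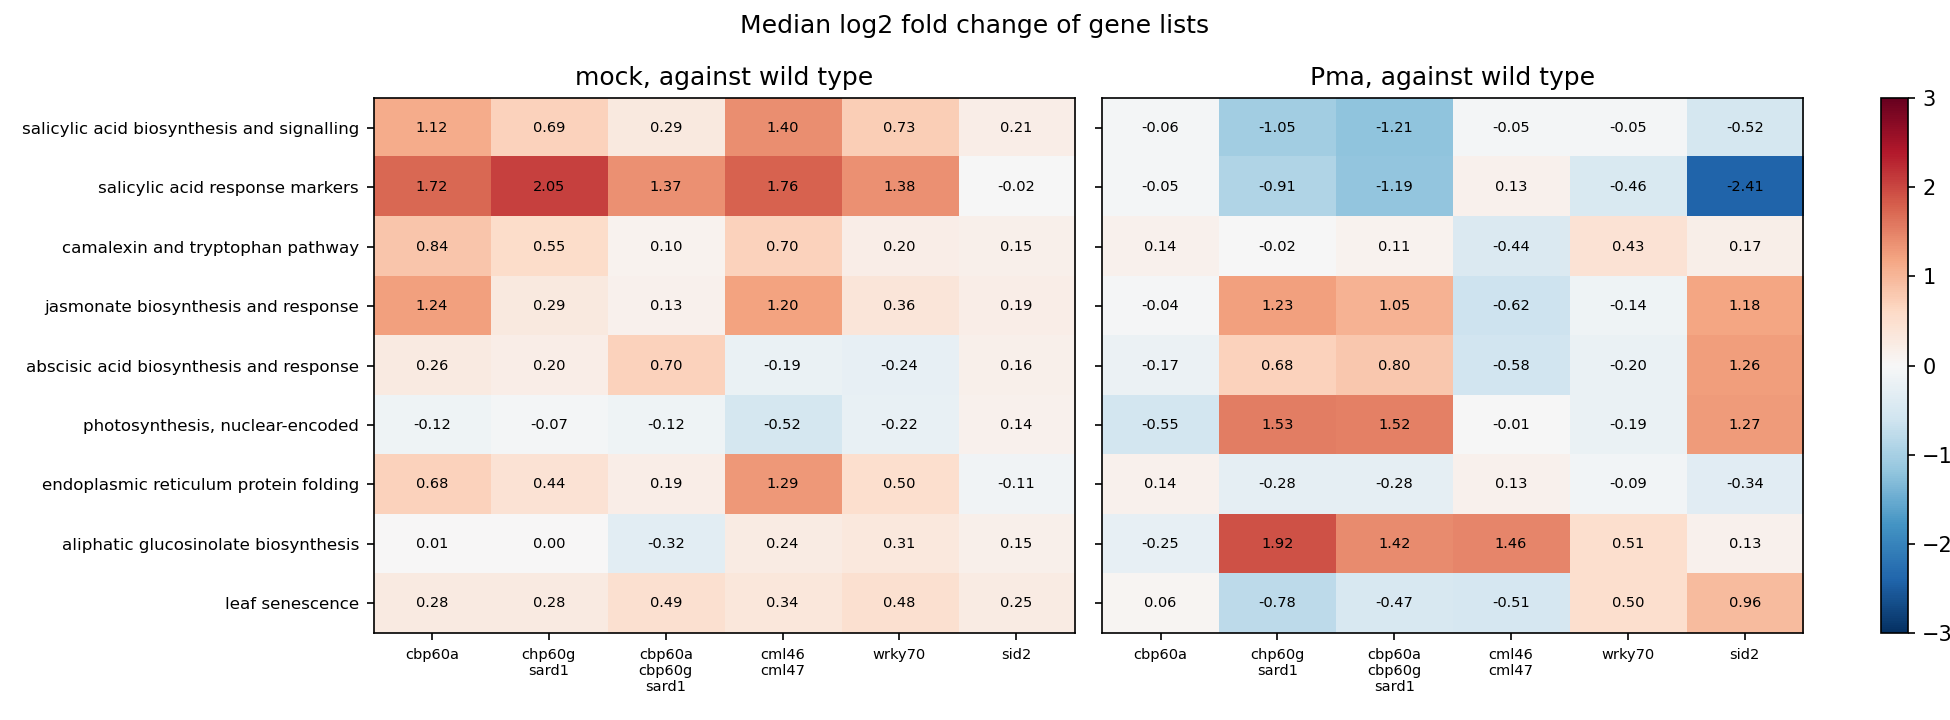
Median log2 fold change of 9 gene lists in each mutant against wild type, in mock (left) and Pma (right), with a colour scale from -3 (blue) to 3 (red). Each cell is 1 list in 1 mutant, and the lowest is -2.41 for the response markers in sid2 Pma.

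In wrky70 Pma leaves 502 genes differed (266 higher, 236 lower), and 174 without the block. The signal peptide gene CLE5 was 41.7-fold higher (14 to 205, adjusted p = 7.19e-09), the antifungal protein OSM34 4.42 ± 0.83, the glucosidase DIN2 3.83 ± 0.62 and ORA59 16.6-fold (4.26 to 142). The P450 gene CYP71B9 was at least 12.7-fold lower, the glucanase gene BG3 lower by -5.20 ± 0.81 (adjusted p = 0.000259), NUDT6 by -2.49 ± 0.62 and WAK1 by -1.89. PR1 (0.13, adjusted p = 0.973), ICS1 (-0.16) and FMO1 (1.38, adjusted p = 0.133) did not pass, and response markers were lower in 1 of 19 cases (median -0.46, list adjusted p = 0.222). With sid2 it shared 90 higher genes (23.7 by chance) and 168 lower (13.3 by chance), and 6 were opposite (r = 0.42, against 0.5 in simulated data, covariance 0.171 against 0.063, difference 0.108). Across different experiments, with no shared library, the mean covariance of wrky70 and sid2 was 0.137 (0.0445 to 0.207 over 6 pairings). Dropping wild type Pma replicate 2 gave 184 genes, wrky70 Pma replicate 2 gave 296 and wild type Pma replicate 3 gave 181.

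In cml46 cml47 Pma leaves 19 genes differed (11 higher, 8 lower), 2 without the block and 34 by DESeq2. The meiosis gene HEI10 was 36.3-fold higher (6.16 to 1470, adjusted p = 0.0418), the peroxidase PA2 17.7-fold (4.59 to 151), the glucosinolate hydrolysis gene ESM1 2.91 ± 0.63 and the cap-binding gene ABH1 1.46 ± 0.30. The stress-induced gene DSI-1VOC was 16.6-fold lower (5.31 to 83.4), the lipase gene MPL1 lower by -2.54 ± 0.51 and ILL5 by -3.43. PR1 (0.64, adjusted p = 0.875) and ICS1 (-0.07) did not pass. No jasmonate gene was called, 6 were lower and 1 higher when adjusted over the list alone (median -0.62, list adjusted p = 6.96e-07, adjusted p = 0.48 with an estimated correlation), and the photosynthesis list had a median of -0.01 and a mean of 0.18. Removal of wild type Pma replicate 1, 2 or 3 gave 5, 5 and 7 genes, and leaving out cml46 cml47 Pma replicate 1, 2 or 3 gave 5, 4 and 186.

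In cbp60a Pma leaves edgeR called 0 genes, with 348 at unadjusted p under 0.05 and 4 by DESeq2. PR1 (0.27) and ICS1 (0.12) stayed near wild type, and the photosynthesis list had a median of -0.55 without any gene called (list adjusted p = 1.14e-19, adjusted p = 0.946 with an estimated correlation). Taking out wild type Pma replicate 3 gave 2 genes. A self-test, made for sid2 in mock and not for this comparison, recovered 24% of genes with a simulated 2-fold change, so small effects of cbp60a are not ruled out.

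The sixth question was whether the response itself differed from that of wild type. In chp60g sard1 the responses of PR1 (-10.00 ± 1.80, adjusted p = 0.00156), ICS1 (-2.82 ± 0.64, adjusted p = 0.00735), WRKY70 (-3.25 ± 0.72, adjusted p = 0.00636) and GRXS13 (-6.68 ± 0.98) were smaller, and that of AOS larger (2.45 ± 0.44, adjusted p = 0.00141). For WRKY70 and, by medians, the response markers, the larger part of the difference came from higher mock levels. WRKY70 was at 557 ± 267 CPM against 108 ± 57.2 in mock and at 1110 ± 570 against 1820 ± 166 in Pma. The marker median was 2.05 above wild type in mock and at -0.91 in Pma. The response differed for 1032 genes (549 higher, 483 lower), and 315 without the block. Response markers had a smaller response in 11 of 20 cases (median -2.74, adjusted p = 0.206 with an estimated correlation), salicylic acid genes in 6 of 20 (median -1.66, adjusted p = 0.263 with an estimated correlation), and photosynthesis genes a smaller fall in 14 of 43 (median 1.60, adjusted p = 0.263 with an estimated correlation). ALD1 (-1.67, adjusted p = 0.634) and PAD3 (-1.37, adjusted p = 0.568) did not pass, and FMO1 is given no value because wild type mock held no count of it. A fit without wild type mock replicate 1 gave 558 genes, wild type Pma replicates 1 and 3 gave 626 and 488, chp60g sard1 mock replicate 3 gave 513 and chp60g sard1 Pma replicate 3 gave 281.

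In the triple mutant 589 genes had a different response (347 higher, 242 lower), and 65 without the block, with PR1 at -7.63 ± 1.80 (adjusted p = 0.0177), ICS1 at -3.09 ± 0.65 (adjusted p = 0.0083) and WRKY70 at -2.89 (adjusted p = 0.0225). Response markers were lower in 6 of 20 cases (median -2.32, adjusted p = 0.309 with an estimated correlation). Higher mock levels were part of this, as the marker median was 1.37 above wild type in mock and at -1.19 in Pma. The triple mutant shared 279 higher (12.6 by chance) and 178 lower genes (7.7 by chance) with chp60g sard1. These chance values take no account of the shared wild type libraries. For camalexin the median (-0.20) and mean (-0.25) were opposite to the test. Omission of wild type mock replicates 1 and 2 gave 218 and 287 genes, wild type Pma replicates 1 and 3 gave 289 and 174, triple mutant mock replicates 1 and 3 gave 194 and 266, and triple mutant Pma replicates 1 and 3 gave 1176 and 66.

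In sid2 the response differed for 262 genes (125 higher, 137 lower), 36 without the block and 399 by DESeq2. PR1 (-8.28 ± 1.94, adjusted p = 0.0242), PCR1 (-7.07 ± 1.25), PCC1 (-4.56 ± 0.81) and WRKY70 (-3.56 ± 0.72, adjusted p = 0.00932) responded less, TT4 (4.92) and the peroxidase GPX7 (4.94) more, and ICS1 did not pass (-4.27 ± 1.19, adjusted p = 0.0533). Response markers were lower in 6 of 20 cases (median -2.82, adjusted p = 0.417 with an estimated correlation). Leaving out wild type mock replicates 1 and 3 gave 60 and 148 genes, wild type Pma replicates 1 and 3 gave 140 and 72, sid2 mock replicates 1 and 3 gave 140 and 89, and sid2 Pma replicates 1 and 2 gave 116 and 62.

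In cml46 cml47 the response differed for 87 genes (19 higher, 68 lower), 8 without the block and 343 by DESeq2. PR1 (-7.74 ± 1.70, adjusted p = 0.0278), CAX3 (-6.60 ± 1.00, adjusted p = 0.00106) and PR2 (-6.11 ± 1.2) responded less, from the higher mock level, and ESM1 more (3.66). Of the 87 genes, 72 were also called in mock and 3 in Pma. Dropping wild type mock replicates 1, 2 and 3 gave 13, 35 and 5 genes, and wild type Pma replicates 2 and 3 gave 45 and 22. Removal of cml46 cml47 mock replicates 1, 2 and 3 gave 178, 17 and 11, and cml46 cml47 Pma replicates 1 and 3 gave 9 and 395.

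In wrky70 17 genes had a different response (4 higher, 13 lower), 1 without the block and 116 by DESeq2, with PR2 at -5.60 ± 1.2 (adjusted p = 0.0453), CAX3 at -4.73 ± 1.02, EXO at -3.44 and the glycosyltransferase UGT73B1 at 3.36. CAX3 (45.2 CPM against 1.43 in mock, 354 against 277 in Pma) responded less from a higher mock level. PR2 was higher in mock (255 against 13.1 CPM) and lower in Pma (570 against 1240), as was EXO (66.5 against 6.17, 30.2 against 70.8). The gene ANK differed in Pma only (28.7 against 28.3 CPM in mock, 35.4 against 448 in Pma). Of the 17 genes, 14 were also called in Pma and 2 in mock, and 5 differed more in mock. The higher share of the 17 genes was 23.5%, and 41.7% with RLE scaling. Taking out wild type mock replicates 1, 2 and 3 gave 2, 11 and 3 genes, wild type Pma replicates 1, 2 and 3 gave 4, 4 and 2, wrky70 mock replicates 1, 2 and 3 gave 2, 82 and 4, and wrky70 Pma replicates 1 and 3 gave 59 and 92. In cbp60a edgeR called 0 genes, with 866 at unadjusted p under 0.05 and 0 by DESeq2, although 11 of 20 response markers were lower when adjusted over the list alone (median -1.83, adjusted p = 0.167 with an estimated correlation). In cbp60a mock 1 library stood apart for the markers PR1 (705, 11.7 and 14.1 CPM) and GRX480 (36.5, 0.783 and 1.28 CPM), which lowers the mean response.

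The last question was what the cbp60a mutation added to chp60g sard1. In Pma 1 gene differed between the triple mutant and chp60g sard1, CBP60A itself (-1.57 ± 0.25, adjusted p = 0.00546). edgeR found 336 genes at unadjusted p under 0.05, DESeq2 called 1 and the fit without the block 0, and leaving out triple mutant Pma replicate 2 or chp60g sard1 Pma replicate 3 gave 0. In mock 0 genes differed (414 at unadjusted p under 0.05, 1 by DESeq2, and 1 without triple mutant mock replicate 2), although the response markers had a list call (median -0.75, adjusted p = 1e-07, adjusted p = 0.503 with an estimated correlation). The effect of cbp60a in both backgrounds correlated at r = -0.12 in mock and 0.11 in Pma, where data without an effect gave 0. Neither value was stable. Single experiments gave 0.12, -0.06 and 0 in mock and 0.15, 0.01 and -0.04 in Pma, and leaving out 1 experiment gave -0.06 to -0.03 in mock and -0.02 to 0.16 in Pma.

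The mock profiles of cml46 cml47 and wrky70 correlated at r = 0.77 (0.55 in simulated data, covariance 0.2 against 0.0667, difference 0.133). Single experiments gave 0.72, 0.42 and 0.78. The profiles of cml46 cml47 and cbp60a correlated at 0.67 (0.52 in simulated data, covariance 0.172 against 0.0665, difference 0.105), and at 0.61, 0.53 and 0.40 in single experiments. The simulated values are for all 3 experiments together and not for a part of them. With cml46 cml47, cbp60a shared 18 of its 28 higher genes (1.1 by chance). Without experiment 1, which holds the cbp60a mock library that stands apart, r of this pair was 0.49, and without that library none of the 28 genes was called. Every comparison with wild type used the same wild type libraries, which may add to all overlaps between mutants. In mock r was 0.57 for cbp60a and wrky70 (0.51 in simulated data with a range of 0.49 to 0.52, covariance 0.1 against 0.0666, difference 0.0339) and 0.40 for chp60g sard1 and sid2 (0.51, difference -0.00631). In Pma r was 0.30 for cbp60a and cml46 cml47 (0.51, difference -0.0213), 0.38 for cml46 cml47 and wrky70 (0.51, covariance 0.0944 against 0.0631, difference 0.0313, with 6 higher genes shared and 0.2 by chance) and 0.29 for cbp60a and wrky70 (0.51, difference -0.0157). The covariance thus exceeded that of the shared controls for cbp60a and wrky70 in mock and for cml46 cml47 and wrky70 in Pma, and was below it for the other 3 of these pairs. With effects from different experiments, which share no library, the mean covariance in mock was 0.151 for cml46 cml47 and wrky70 (0.0329 to 0.259 over 6 pairings), 0.137 for cml46 cml47 and cbp60a (0.0348 to 0.303) and 0.0561 for cbp60a and wrky70 (0.0173 to 0.145). For cml46 cml47 and wrky70 in Pma it was 0.0111 (-0.098 to 0.121), so the excess of that pair was not seen across experiments.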

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

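In this part the other splits of the libraries and the fits without 1 library were fixed in advance, and all other tests were chosen only after the result was seen.

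The Pma response of chp60g sard1 differed from that of wild type in 1032 genes, among them 11 of 20 salicylic acid markers with a smaller response (the list call was lost at adjusted p = 0.206 with an estimated correlation). Weaker infection of these leaves would have needed the jasmonate median to differ by -2.77, since the markers lost 66.2% of the wild type response on the log2 scale. By medians the larger part of that loss is a raised mock level, as the marker median was 2.05 above wild type in mock and at -0.91 in Pma. The jasmonate median differed by 0.67 instead (quartiles -0.22 to 1.24, 20 of 30 genes with a larger response), and in Pma alone it was 1.23 above wild type. A weaker infection that lowers both hormone groups alike was thus excluded, while one that relieves jasmonate genes was not tested. A few genes taking most of the counts would have needed a share of 85% for the 10 largest genes in the Pma libraries. These genes held 7.55 ± 1.13% (SD, n = 3), so this was excluded as the source of a median fall of -2.74. That fall is the difference in response. The smaller fall of the markers in Pma itself (median -0.91) would need a smaller share, which was not computed. For the markers a raised mock level was the larger part by these medians, and it was not tested gene by gene. Among the 1032 genes, 271 differed more in mock than in Pma. A direct loss of induction by CBP60G and SARD1 is a biological explanation that these data did not test.

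The response of cml46 cml47 differed from that of wild type in 87 genes, 68 of them lower. A raised mock level fits, because 69 of the 87 differed more in mock than in Pma (median 2.89 in mock, 0.11 in Pma). Carried Pma material would have brought all its genes into the mock libraries at the same share of the Pma level. The 581 genes higher in mock needed a share of 24.3 ± 5.6% (mean of the medians, SD, n = 3), and 20 genes absent from wild type mock reached 1.54 ± 0.77%. With the Pma level of any of the 7 genotypes as the source, the needed share (lower quartiles from 8.83%) stayed above the reached share (upper quartiles to 4.08%) in every experiment, so carry-over was excluded as the sole cause, and whether the mutation itself raises the mock level was not tested apart from that.

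The 28 genes higher in cbp60a mock were lost without any 1 of 4 libraries, which were cbp60a mock replicate 1 and the 3 wild type mock libraries (0 genes each). The count was 119 and 304 without cbp60a mock replicates 2 and 3, so a cbp60a library that stands apart fits, while the loss without a wild type library needs no such library. In that replicate the 28 genes needed a share of 32.9% of the cbp60a Pma level (lower quartiles from 15.5% over 7 sources), and 29 genes absent from wild type mock reached 2.97% (upper quartiles to 5.95%), so carry-over of Pma material was excluded as the sole cause there. A defence response of that plant was not tested.

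The response of the triple mutant differed from that of wild type in 589 genes. For wrky70 the response differed in 17 genes, and for sid2 in 262.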

How the results depend on the processing

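The trended dispersion was chosen after the data were seen, and all other settings were fixed in advance. Without the replicate block, 12 of the 27 counts kept their label and 15 were weaker. In mock, cbp60a went from 28 to 0 genes, chp60g sard1 from 70 to 10, cml46 cml47 from 795 to 315 and wrky70 from 9 to 3. In Pma, chp60g sard1 went from 1986 to 1171, the triple mutant from 1533 to 861, cml46 cml47 from 19 to 2, wrky70 from 502 to 174 and sid2 from 2200 to 1127. The difference in response went from 1032 to 315 in chp60g sard1, 589 to 65 in the triple mutant, 87 to 8 in cml46 cml47, 17 to 1 in wrky70 and 262 to 36 in sid2, and the triple mutant against chp60g sard1 in Pma from 1 to 0. Of the named genes 953 kept their call and 161 lost it, and 4 single lists lost and 3 gained a call. The block changed no other call, and similarity was not run without it.

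DESeq2 called more genes in 9 of 27 comparisons: 134 in cbp60a mock, 15 in triple mutant mock, 56 in wrky70 mock, 4 in cbp60a Pma, 34 in cml46 cml47 Pma, 343, 116 and 399 for the difference in cml46 cml47, wrky70 and sid2, and 1 in triple mutant against chp60g sard1 mock. It also called CBP60A in cbp60a Pma (-1.16, adjusted p = 0.0462). Of the named genes 28 lost their call and 17 gained one. With RLE size factors cbp60a mock went to 0 genes and 19 named genes lost their call. The cause was not tested.

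Without the filter cbp60a mock went to 0 genes, wrky70 mock to 22, cbp60a Pma to 1 and cml46 cml47 Pma to 34, and 31 named genes lost their call. The response sizes moved to -1.90 for the fall in wild type, -1.81 in cbp60a, -1.48 in chp60g sard1, -1.43 in cml46 cml47 and -1.65 in sid2, and to 1.62, 1.69 and 1.93 for the rise in chp60g sard1, the triple mutant and sid2. The trended dispersion gave 0 genes in cbp60a mock, 1 in sid2 mock and 9 for the difference in wrky70. Fits of mock libraries alone gave 59 genes in cbp60a, 132 in chp60g sard1, 13 in the triple mutant, 2157 in cml46 cml47, 139 in wrky70, 21 in sid2 and 1 in the triple mutant against chp60g sard1, and a fit of Pma libraries alone gave 1 in cbp60a. Of 204 list calls 6 held with the estimated correlation, and 198 single lists were weaker with it.

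Leaving out 1 experiment or 1 library gave these ranges. In mock the counts were 0 to 304 for cbp60a, 0 to 48 for chp60g sard1, 0 to 10 for the triple mutant, 90 to 902 for cml46 cml47, 0 to 74 for wrky70 and 0 to 2 for sid2. In Pma they were 0 to 2 for cbp60a, 506 to 1897 for chp60g sard1, 226 to 2058 for the triple mutant, 2 to 186 for cml46 cml47, 18 to 564 for wrky70 and 454 to 1724 for sid2. For the difference they were 28 to 1055 in chp60g sard1, 6 to 1176 in the triple mutant, 0 to 395 in cml46 cml47, 0 to 92 in wrky70 and 2 to 253 in sid2, and for the triple mutant against chp60g sard1 0 to 1 in mock and 0 to 1 in Pma. The infection counts stayed between 6679 and 9682. Fewer libraries also mean less power, which was not separated from the effect of any 1 library.

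CML46 in cml46 cml47 mock ranged from -3.95 to -2.85, ICS1 in sid2 mock from -4.48 to -3.09 and CBP60A in the triple mutant in Pma from -1.30 to -0.83, each losing its call without replicate 2 or 3. The response size ranged from 1.72 to 1.78 for the rise in chp60g sard1 and from 1.80 to 1.88 in the triple mutant. The similarity of cbp60a and cml46 cml47 ranged from 0.49 to 0.68 in mock and from 0.21 to 0.47 in Pma, and that of cbp60a in both backgrounds in Pma from -0.02 to 0.16, with the sign turned without replicate 1. List calls ranged from 190 to 235. The direction turned for aliphatic glucosinolates in triple mutant mock (adjusted p = 0.0012 to 0.911, the highest without replicate 1), jasmonate in wrky70 mock (0.00175 to 0.836, the highest without replicate 3), photosynthesis in cml46 cml47 Pma (0.00425 without replicate 1, up to 0.554) and protein folding in the difference of cbp60a (0.000382 to 0.402, the highest without replicate 1). Of the named genes 106, 251 and 247 lost their call without replicates 1, 2 and 3, and none turned direction. No shared call changed sign in any alternative.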

Other observations

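In this part the splits were fixed in advance, and all other tests were chosen only after the result was seen.

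PR2 and PR1 parted in the infected mutants, in values chosen after they were seen. PR2 stood at 1240 ± 537 CPM in wild type Pma, 2590 ± 806 in chp60g sard1, 2040 ± 393 in the triple mutant and 1210 ± 671 in sid2, whereas PR1 was at 6250 ± 1550, 103 ± 127, 188 ± 246 and 49.9 ± 25 in the same groups (SD, n = 3). In wrky70 PR2 varied between experiments (1440, 187 and 84.9 CPM). PR1 in chp60g sard1 Pma was at 248, 50 and 11.7 CPM, so its level also differed by experiment.

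MRD1, a gene of unknown function, was at 21.9 ± 0.845 CPM in sid2 mock and 30.9 ± 7.3 in sid2 Pma, and 148-fold higher there than in wild type Pma (26.2 to 5900). Some other libraries carried it as well, with 35.6, 13 and 0 CPM in cml46 cml47 Pma and 27.2 in cml46 cml47 mock replicate 3. AGD1, a membrane traffic gene, was 236-fold higher in chp60g sard1 Pma (41.9 to 9360) but stood at 48.6 and 77.1 CPM in replicates 1 and 3 alone. AT1G75945 was lower in sid2 in mock (-7.40) and in Pma (-5.16, adjusted p = 1.19e-05) and lies on chromosome 1, start 28515245, end 28515916 (TAIR10.1), near ICS1 (start 28070295, end 28074177). These values were chosen after they were seen, and a difference in the plant line is 1 hypothesis that genotyping of the seed would test.

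Variants linked to the mutated loci would bring an excess of changed genes within 1 Mb. The Pma comparisons had 75 such genes in chp60g sard1 (69.2 by chance, exact hypergeometric p = 0.243), 16 in wrky70 (11.2, p = 0.0998) and 56 in sid2 (52.2, p = 0.305). In the triple mutant 87 were found where 88.5 came by chance (exact hypergeometric p = 0.586). No excess passed, but a few linked genes would not show among so many calls (1521 in the triple mutant), so linked variants stay open in these 4 mutants. In cml46 cml47 0 of the 18 called genes counted lay there (0.6 by chance), so none of these calls was of a gene in that window.

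Clock genes differed between the experiments. LHY, a morning gene, was higher in experiment 2 than in the others by 3.28 ± 0.46 (SD, 14 of 14 groups), with 5.7, 104 and 14.2 CPM in mock, and the evening gene CCR2 lower by -4.81 ± 0.59. By the sign of the mean, 18 of 19 listed clock genes differed as leaves taken at another time of day would need, so a shift in sampling time fits. PRR7 (-0.28) had the other sign, and PRR9 (0.58 ± 0.74) was higher in only 9 of 14 groups. That count set experiment 2 against the others together, although experiments 1 and 3 also differed from each other. In mock CCR2 was at 2130, 35.5 and 341 CPM in experiments 1, 2 and 3, and FKF1 at 14.1, 1.83 and 2.52. PRR7 was closer in experiments 1 and 3 (149 and 159 CPM). Which experiments were shifted was thus not settled. A shift may add to the gain from the experiment block, and sampling times in the records would test that.

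Every comparison has 10 splits into 3 and 3, too few for a share under 0.05. In the other splits a real difference lies inside the groups and raises their spread, so a low count there is no null level. In wild type infection 1 split, the real one, called as many genes as the real count of 10051, and the highest other was 1. The highest other was 0 for cbp60a (9585), 0 for chp60g sard1 (8699), 12 for the triple mutant (8843), 1 for cml46 cml47 (8662), 1 for wrky70 (9197) and 0 for sid2 (9484), and only 1 split, the real one, was as large in each. In mock only 1 split was as large for cbp60a (28, highest other 16), chp60g sard1 (70, 0), cml46 cml47 (795, 5), wrky70 (9, 3) and sid2 (2, 0), whereas 10 of 10 were for the triple mutant (0, 0). In Pma only 1 was as large for chp60g sard1 (1986, 1), the triple mutant (1533, 450), cml46 cml47 (19, 1), wrky70 (502, 32) and sid2 (2200, 1), and 10 of 10 for cbp60a (0, 0). For the difference 1 was as large for chp60g sard1 (1032, 1), the triple mutant (589, 7), cml46 cml47 (87, 0), wrky70 (17, 2) and sid2 (262, 0), and 10 of 10 for cbp60a (0, 0).

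For the triple mutant against chp60g sard1 10 of 10 splits were as large in mock (0, highest other 1) and 5 of 10 in Pma (1, highest other 128). Only 4 of the 10 splits part all 3 pairs of an experiment, and the other 6 hold a whole pair on each side. All splits kept the experiment block, so differences common to all groups of an experiment were taken out. What these groups alone showed in an experiment was not. Among splits that part all pairs the highest other was 0 for cbp60a mock, cml46 cml47 mock, wrky70 mock, wrky70 Pma and the triple mutant against chp60g sard1 in Pma, and 2 for the triple mutant in Pma. The 128 genes, like the 450, 32 and 16, came from splits that hold a whole pair, which points to structure among the samples larger than the 1 gene of the real split.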
